A study of Mus musculus with 12 samples.

How the data were processed

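RNA from the left ventricle of 12 mouse hearts was measured on Affymetrix arrays, which the file headers name as MoGene 2, with 1 array per heart. There were 3 hearts in each of 4 groups: sham, placebo mI/R, sleeptime captopril mI/R and waketime captopril mI/R. The authors prepared RNA from snap-frozen tissue with the Qiagen miRNeasy kit and labelled 500 ng of total RNA as biotinylated cRNA. The deposited values are on a log2 scale, as read here, and have the median of each probe set over the 12 arrays subtracted. The base of the logarithm is not stated and was read as log2; the subtraction was found in the values, since the median of every probe set was 0. The normalization that the authors applied is not given in the sources used here. The 2 deposited files held the same values cell by cell, and 1 was used.

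After the subtraction the medians of the arrays lay between -0.0051 and 0.0037, and the values no longer held a level per gene. The rounding steps of the values were read to recover a lower bound of the level, at a tolerance of 0.12 of a step. Over the readable arrays of each probe set, at least 6, all 34351 probe sets had uncentred values of 4 or above. On these arrays 2149 (6.26%) lay at 8 or above and 0 at 16 or above. The number of arrays limits the precision: the residual degrees of freedom were 8 and the prior degrees of freedom 2.21. The median standard deviation of a gene within groups, as moderated by limma toward its prior, was 0.064 on the log2 scale. No 2 arrays of a group were copies; their highest correlation was 0.564.

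Probe sets of the main category with exactly 1 gene symbol were used, 29985 of 34351; 4366 were left out, 2478 without a symbol and 1888 with several. Where a gene had more than 1 probe set (384 genes), their mean was taken, which gave 29469 genes. Of the used probe sets 26651 were of cross-hybridization type 1 and 3334 of type 3. Of the 24707 with an Entrez identifier in the reference table, 95.7% had the same symbol there and 99.1% overlapped their gene in GRCm38.p6; the build of the deposited coordinates is not given in the sources used here.

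Differences were computed with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with 1 mean per group over all 12 hearts, and two-sided p values were adjusted by Benjamini-Hochberg over the 29469 genes with a threshold of 0.05. The plan, written before the data were examined, had held a filter on dim probe sets, a variance trend with the mean, the choice of the probe set with the highest mean and a quantile normalization. None can be computed from values without a level; they were dropped before any call was seen, and the median centring of arrays was run instead. The comparisons were placebo mI/R with sham, sleeptime and waketime captopril each with placebo mI/R, sleeptime with waketime captopril, and, as further comparisons, captopril at either time with placebo mI/R and each or all of the treated groups with sham. Intervals are 95% intervals of the moderated t.

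For the lists, 33 sets of gene symbols were written down from general knowledge: extracellular matrix, activated fibroblast, fetal and hypertrophic programme, sarcomere, ion channels, electron transport, fatty acid oxidation, tricarboxylic acid cycle, glycolysis, clock, renin-angiotensin and kinin, natriuretic, adrenergic and endothelin signalling, macrophage and neutrophil markers. Others were lymphocyte, mast cell, cytokines, interferon, MHC class II, complement, endothelial, smooth muscle, epicardial, adipocyte, atrial, nerve, cartilage and bone, red blood cell, cell cycle, heat shock, immediate early, glucocorticoid and fasting response, and sex-linked genes. They held 687 symbols, of which 665 were found, and Per2 and Ren1 are among those not analysed here. Some lists share genes, so their results are not independent. Each list of at least 5 genes was tested with camera at a preset correlation between genes of 0.01, adjusted over the 33 lists, and again with an estimated correlation and with fry. Members were counted by the adjusted p over all genes and again adjusted over the list alone. The latter count is not corrected over the 33 lists or over the comparisons.

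The genes to be named in a comparison were fixed as the 10 largest rises and the 10 largest falls among the called genes, or, with fewer than 5 calls, the 5 higher and the 5 lower genes with the smallest p. To these came up to 4 members of each called list with the smallest p in its direction, and always, among others, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn, Timp1, Ace, Agt, Agtr1a, Bdkrb1, Bdkrb2, Arntl, Per1, Nr1d1 and Dbp. Genes without a symbol, predicted genes, small RNAs, pseudogenes, immunoglobulin and T cell receptor segments and olfactory or vomeronasal receptors were left out of the first part, and not every gene under the rule is printed.

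A score per heart was the mean of the genes called higher in placebo than in sham hearts minus the mean of those called lower, compared by an exact two-sided permutation test. Alternatives were a block for the replicate number, array weights, a robust variance, median centring, a 1.5-fold minimum, a fit of the compared groups alone and each heart left out in turn. Chosen after seeing the data were the probe set with the most probes, cross-hybridization type 1 alone, bright probe sets alone (uncentred values of 8 or above, 1935 genes), the set of array-name numbers as a covariate and fits within a set. Also chosen then were a score from other genes and a covariate for Myh7. Leaving out placebo replicate 2 or waketime replicate 2 was planned for the called lists. For the lists not called it was added after seeing the data. Correlations between differences and the overlap of calls were set against 100 simulated data sets of unchanged groups.

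The procedure was tested on simulated data with 200 changed genes among 29469 in 5 runs. It recovered 85.1%, 98.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 4.8% false calls and 0 calls between the unchanged dosing groups. The changed genes were drawn at random and the noise independently for each gene. The recovery is thus an average mostly over genes of small spread and says little of more variable genes. A simulated shift of 0.3 in the extracellular matrix list was found by camera in 5 of 5 runs, and no other list was called. As the simulated genes were independent, these runs cannot show how often lists of genes that move together are called falsely. Further tools were data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.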

Results

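Gene expression was measured in the left ventricle of 12 C57Bl/6N mice, 1 array per heart, in 4 groups of 3 hearts. The groups were sham-operated mice, mice that received a placebo after myocardial ischemia/reperfusion (mI/R), and mice given captopril after mI/R at sleeptime or at waketime. Captopril inhibits angiotensin-converting enzyme, and a mouse, being nocturnal, sleeps in the light phase. All hearts were taken 14 days after mI/R, in mice 10 weeks old and 3 hours into the dark phase. The values covered 29469 genes on a log scale, read as log2, as differences from the median of the 12 hearts, so that they gave differences between hearts and no levels. The number of arrays limits the precision. The first principal component held 40.6% of the variance and placed the sham hearts between -17.5 and -16.3 and every mI/R heart at -4.3 or above. Placebo replicate 2, at 25.5, and waketime replicate 2, at 11.8, lay farthest to the other side. The array names carry a number of unstated meaning, and the numbers were cut at their widest gap into 2 sets. The higher set holds the 3 sham, the 3 sleeptime and 1 waketime array, and the lower holds the 3 placebo and 2 waketime arrays.

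The comparison of placebo mI/R with sham hearts asked which genes differed 2 weeks after the injury. Genes of the extracellular matrix rose the most. Postn, which encodes the matricellular protein periostin of activated fibroblasts, was 8.08-fold higher (95% interval 5.88 to 11.09, n = 3 per group, limma adjusted p = 0.000613). It lay at 0.77 ± 0.11 (SD) in placebo and -2.25 ± 0.14 in sham hearts. The fibrillar collagen genes Col3a1 and Col1a1 rose 7.3-fold (4.58 to 11.62; adjusted p = 0.00298) and 5.87-fold (3.75 to 9.17; adjusted p = 0.00363). Of the 50 measured members of the extracellular matrix list, 43 rose and none fell, with a median difference of 1.15 on the log2 scale, and adjusted over the list alone 47 rose. Genes that the adult ventricle re-expresses under load rose as well: Acta1, the skeletal muscle actin, 3.22-fold (2.39 to 4.35) and Nppa, which encodes atrial natriuretic peptide, 2.68-fold (2.15 to 3.35). Nppb rose 2.13-fold (1.57 to 2.89) and Myh7, the slow myosin heavy chain, 2.09-fold (1.44 to 3.02).

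In all, 1688 genes differed between placebo mI/R and sham hearts, 1065 higher and 623 lower, by a median of 0.39 on the log2 scale, where 5654 genes had an unadjusted p under 0.05 and 1473 were expected by chance. For each of the 1688, the 3 placebo hearts lay entirely above or below the 3 sham hearts; 23.9% of all genes did so, and chance alone gives 10%. At least 1.5-fold differences were seen in 391 of these genes, 358 higher and 33 lower. Other large rises were those of Cilp (2.47 ± 0.22 SE), Sfrp2 (2.37 ± 0.3), Fn1, which encodes fibronectin (2.24 ± 0.32), Col14a1 (2.21 ± 0.23), Col1a2 (2.14 ± 0.26), the complement gene C4b (2.09 ± 0.24) and Angptl7 (2.02 ± 0.38), all log2 differences. The falls were smaller, the largest being those of Penk, which encodes proenkephalin (-0.85 ± 0.14), Dhdh (-0.8 ± 0.1) and the carboxylesterase gene Ces1d (-0.78 ± 0.1). Next came Kcnv2 (-0.78 ± 0.2), Adhfe1 (-0.77 ± 0.11) and the striated muscle ribosomal protein gene Rpl3l (-0.76 ± 0.12). Of the called genes, 161 were predicted genes, small RNAs, pseudogenes or receptor segments and are not named.

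Several gene lists fixed beforehand moved together in placebo hearts. By camera, 19 of the 33 lists differed, 13 higher and 6 lower, and none did with an estimated correlation between genes, where the smallest adjusted p was 0.134. Matrix (camera adjusted p = 1.01e-51), macrophage and monocyte markers (1.97e-24), cell cycle (4.6e-20), activated fibroblast markers (5.93e-17), complement (1.4e-14) and the fetal and hypertrophic programme (2.55e-09) each had an adjusted p = 0.134 with an estimated correlation. Of 29 macrophage and monocyte markers, 20 rose and 25 did so adjusted over the list alone, among them Ms4a7 (3.48-fold), the lipid-sensing receptor gene Trem2 (2.23-fold) and Cd68 (2.13-fold). Of 31 cell cycle genes, 18 rose (25 adjusted over the list alone, where 1 fell), with Ccna2, which encodes cyclin A2, 1.81-fold and Mcm5, a subunit of the replicative helicase, 1.49-fold higher. Of 20 activated fibroblast markers 12 rose (16 adjusted over the list alone), led by Wisp2 (3.27-fold) and Meox1 (3.19-fold), of 16 complement genes 9 rose (13), and of 20 fetal and hypertrophic genes 7 rose (10), including Ankrd1 (2.01-fold). The complement and macrophage lists share C1qa, C1qb and C1qc. The macrophage count was 10, 12 and 12 without sham replicate 1, 2 or 3. That of the cell cycle was 6 and 8 without sham replicate 1 or 2 and 7 without placebo replicate 2, and that of complement 5 and 4 without sham replicate 1 or 3 and 5 without placebo replicate 2. The fetal count was 3 without sham replicate 1, and the fetal median 0.53 without placebo replicate 3.

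Interferon response genes were higher, with 9 of 26 called (18 adjusted over the list alone) and Ifit1 up 1.78-fold; their camera adjusted p was 2.2e-14, against an adjusted p = 0.166 with an estimated correlation. Cytokines and chemokines (5 of 29 called, 12 higher and 1 lower adjusted over the list alone, Ccl6 2.5-fold), endothelial markers (3 of 23, 10) and immediate early genes (2 of 26, 3) were higher by camera, each with an adjusted p = 0.211 with an estimated correlation. Epicardial markers (1 of 16 called, Aldh1a2 1.56-fold) and genes of MHC class II antigen presentation (0 of 7 called, median 0.59) were also higher, each with an adjusted p = 0.282 with an estimated correlation. The lymphocyte list, with 0 of 21 members called and a median of 0.085, was higher at a camera adjusted p of 0.00187 and an adjusted p = 0.434 with an estimated correlation. Placebo replicate 2 stood far above the other placebo hearts in the immune lists, by 1.04 in MHC class II, 0.62 in lymphocyte markers, 0.56 in macrophage markers, 0.51 in cytokines and 0.44 in interferon genes. Without that heart the macrophage median was 0.64 in place of 0.82, the interferon median 0.27 in place of 0.39, and the MHC class II median 0.22 in place of 0.59. The lymphocyte list was then no longer called (median -0.003, camera adjusted p = 0.437). The count of called interferon genes was 5 without it, and 4 and 3 without sham replicate 1 or 3. For cytokines it was 1, 2 and 1 without sham replicate 1, 2 or 3 and 10, 3 and 3 without placebo replicate 1, 2 or 3. For endothelial markers it was 0 without placebo replicate 2 and 1 without sham replicate 1 or 3 or placebo replicate 1 or 3, with a median of 0.25 without sham replicate 2. For immediate early genes it was 1 without any heart of the pair of groups. Without placebo replicate 1, 3 genes of MHC class II and 1 lymphocyte gene passed.

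Lists of mitochondrial metabolism and ion channels had lower medians in placebo hearts. Fatty acid oxidation had a median of -0.32 (camera adjusted p = 1.08e-14) and ion channels one of -0.26 (4.85e-07), each with an adjusted p = 0.169 with an estimated correlation. Of 28 fatty acid oxidation genes 13 fell and none rose, and 23 fell adjusted over the list alone, with the transporter gene Slc27a1 at 0.7-fold and Mlycd, malonyl-CoA decarboxylase, at 0.71-fold. Among the 21 ion channel genes 8 fell (11 adjusted over the list alone), among them Kcnj3 (0.67-fold) and the ATP-sensitive potassium channel subunits Abcc9 (0.7-fold) and Kcnj11 (0.71-fold). The tricarboxylic acid cycle (3 of 16 called, 12 adjusted over the list alone; median -0.19; Idh2 0.82-fold) had an adjusted p = 0.244 with an estimated correlation. For the electron transport chain (7 of 56, 26 adjusted over the list alone; median -0.18; Sdha 0.79-fold) it was an adjusted p = 0.282 with an estimated correlation. Sarcomere genes (2 of 29 called, 7 adjusted over the list alone; median -0.084; Myl2 0.81-fold) were lower with an adjusted p = 0.311 with an estimated correlation. The 5 sex-linked genes (0 called, 2 lower adjusted over the list alone; median -0.11) were lower with an adjusted p = 0.282 with an estimated correlation. The sex-linked list was not called without sham replicate 1 or 3 (medians -0.1 and -0.13) or placebo replicate 1 or 2 (-0.1 and -0.12). The count of called fatty acid oxidation genes was 0, 1 and 4 without sham replicate 1, 2 or 3 and 6 and 2 without placebo replicate 1 or 2, and that of ion channels 4, 3 and 4 without a sham heart and 3 lower and 1 higher without placebo replicate 2. That of electron transport was 0 without sham replicate 1, 2 or 3 and 2 without placebo replicate 2 (median -0.11), that of the tricarboxylic acid cycle 0, 1 and 0 without a sham heart and 1 without placebo replicate 2, and that of sarcomere genes 0, 0 and 1 and, without placebo replicate 2, 0 (median -0.05).

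The remaining 14 lists were not called in this comparison. The renin-angiotensin and kinin list went both ways (median -0.022, camera adjusted p = 0.655). It had 5 of 24 members higher and 3 lower, and without placebo replicate 2 it had 2 higher and 1 lower. Its gene for the captopril target, Ace, rose 1.66-fold (1.34 to 2.05; adjusted p = 0.0155), and the gene for the angiotensin II type 1a receptor, Agtr1a, fell to 0.71-fold (0.62 to 0.82; adjusted p = 0.0142). Agt (-0.07), Bdkrb1 (-0.03) and Bdkrb2 (-0.08) did not pass. Timp1, an inhibitor of matrix metalloproteinases, rose 3.87-fold. Clock genes had a median of -0.085, with 0 of 21 higher and 2 lower, and with 0 lower without placebo replicate 2. Arntl (-0.12), Per1 (-0.35), Nr1d1 (-0.03) and Dbp (0.03) did not pass. Nor did Myh6, the adult myosin heavy chain (-0.15, adjusted p = 0.147). The other medians were -0.047 in glycolysis, -0.002 in natriuretic, adrenergic and endothelin signalling, 0.027 in neutrophil, -0.039 in mast cell, 0.034 in smooth muscle and -0.007 in adipocyte markers. They were 0.12 in atrial, -0.062 in nerve, 0.054 in cartilage and bone and -0.001 in red blood cell markers, -0.013 in heat shock and -0.12 in glucocorticoid and fasting response genes. Without placebo replicate 2 they were -0.119 in atrial, 0.116 in cartilage and bone, -0.007 in glycolysis and 0.037 in natriuretic, adrenergic and endothelin signalling genes. In that setting neutrophil markers were at 0.008, adipocyte at -0.029, nerve at -0.04 and red blood cell markers at 0.021, and heat shock genes at 0.003.

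Sham and placebo arrays never share a set of array-name numbers, so the group and the set can be separated only through the waketime hearts. With the set as a covariate, chosen after seeing the data, 3 genes passed (Ckap2, Scarna6 and Zdhhc15, named after their values were seen). The median size of the 1688 differences was then 0.38 with a median SE of 0.141 in place of 0.078. All 1688 kept their sign, and 1109 of them had an unadjusted limma p under 0.05. As these genes were chosen for this difference, the kept signs say little. Under this covariate Postn was at 2.75, Acta1 at 1.83 and Myh7 at 0.55. The count also fell to 712, 876 and 784 without sham replicate 1, 2 or 3 and to 769 without placebo replicate 2. It was 1006 in a fit of the placebo and sham hearts alone and 650 among the 1935 genes whose probe sets read as bright, a set chosen after seeing the data. Myh7 was not called without sham replicate 1 or 2 (0.97 and 0.98) or placebo replicate 1, 2 or 3 (1.11, 0.94 and 1.13). Ace was not called without sham replicate 1 or 3 (0.69 and 0.7), and Nppb (1.06) and Agtr1a (-0.46) not without sham replicate 1.

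**Figure D1:**
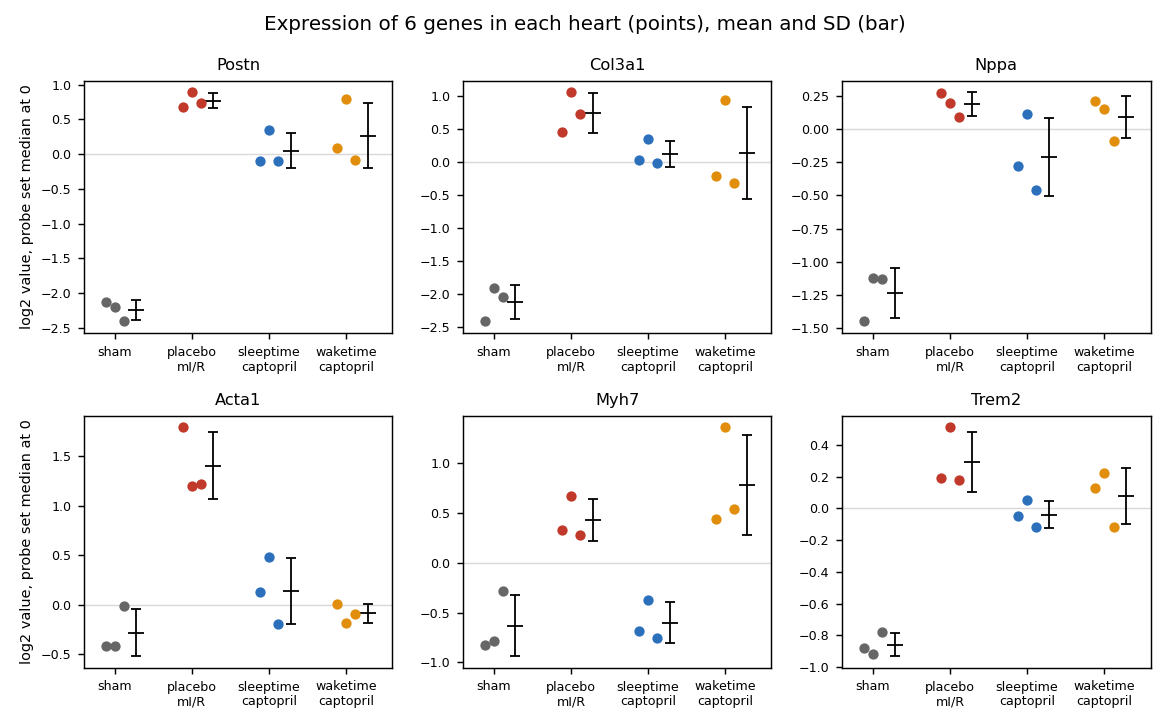
Log2 values of Postn, Col3a1, Nppa, Acta1, Myh7 and Trem2 in each of the 12 hearts, with each gene's median over the hearts at 0; points are hearts and bars the mean and SD of the 3 hearts of a group. Postn lay at -2.25 ± 0.14 in sham and 0.77 ± 0.11 in placebo hearts, and Myh7 at -0.6 ± 0.2 in sleeptime and 0.78 ± 0.51 in waketime hearts.

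In the annotation deposited with the values, Postn (transcript cluster 17397575) spans chromosome 3 from 54361107 to 54391041 on the plus strand and Col3a1 (17212461) chromosome 1 from 45311538 to 45349706 on the plus strand. Nppa (17421545) lies on chromosome 4 from 148000722 to 148002079 (plus), Acta1 (17513995) on chromosome 8 from 123891767 to 123894751 (minus) and Myh7 (17306577) on chromosome 14 from 54970684 to 54994634 (minus). Trem2 (17338416) spans chromosome 17 from 48346401 to 48352273 (plus), Ace (17257444) chromosome 11 from 105967945 to 105989964 (plus) and Agtr1a (17286271) chromosome 13 from 30336356 to 30382867 (plus). The genome build was not stated in the sources used here; 99.1% of 24707 matched probe sets overlapped their gene in GRCm38.p6.

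The next comparison asked how the left ventricle of mI/R mice given captopril at sleeptime differed from that of mice given placebo. No gene passed the test, and the differences below are values. Medians opposite in sign to those of placebo against sham were, among others, -0.45 in the extracellular matrix, -0.41 in the interferon response and -0.26 in the cell cycle, and 0.22 in fatty acid oxidation and 0.17 in ion channels. Both differences use the placebo hearts, with opposite sign, so opposite medians can arise without an effect of captopril. Acta1 stood at 0.42-fold of placebo (95% interval 0.31 to 0.56, n = 3 per group, adjusted p = 0.161), Myh7 at 0.49-fold (0.34 to 0.71; adjusted p = 0.213) and Postn at 0.61-fold (0.44 to 0.83; adjusted p = 0.28). Genes with the smallest p were Ch25h, the cholesterol 25-hydroxylase (-0.55 ± 0.06 SE, adjusted p = 0.109), Mybl1 (-0.31 ± 0.04), the interferon-induced Oas1g (-0.75 ± 0.11) and Smyd5 (-0.23 ± 0.04). On the higher side they were Cyb5d2 (0.23 ± 0.03), Ubxn2a (0.38 ± 0.05), Tlcd1 (0.36 ± 0.06), Tob1 (0.3 ± 0.05) and Dhx16 (0.17 ± 0.03).

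By camera 16 lists differed between sleeptime captopril and placebo, 6 higher and 10 lower, and 0 with an estimated correlation. The lists lower in sleeptime hearts were the extracellular matrix (camera adjusted p = 1.28e-21; Thbs4 -0.6, Vcan -0.45), activated fibroblast markers (median -0.16), cytokines (-0.21), MHC class II (-0.71) and complement (-0.33), each with an adjusted p = 0.274 with an estimated correlation. Interferon (Ifit1 -0.67, Gbp3 -0.57), cell cycle (Kif11 -0.36, Bub1b -0.26) and fetal genes (median -0.2, Ankrd1 -0.52) were lower as well, each with an adjusted p = 0.251 with an estimated correlation. Macrophage markers (median -0.36, Trem2 -0.33) had an adjusted p = 0.298 with an estimated correlation, and lymphocyte markers (-0.11) an adjusted p = 0.517 with an estimated correlation. Higher were ion channels (Kcnj11 0.32; adjusted p = 0.251 with an estimated correlation), fatty acid oxidation (Eci1 0.31) and sex-linked genes (median 0.14), the last pair each with an adjusted p = 0.274 with an estimated correlation. The tricarboxylic acid cycle (0.13; adjusted p = 0.298 with an estimated correlation), electron transport (0.11; adjusted p = 0.299 with an estimated correlation) and sarcomere lists (0.039; adjusted p = 0.517 with an estimated correlation) were higher too. Adjusted over the list alone, 18 cell cycle, 15 interferon, 15 matrix, 9 fetal and 1 cytokine gene were lower, and 8 ion channel, 6 fatty acid oxidation and 1 sarcomere gene were higher. None of them passed over all genes. All are measured against the same placebo hearts, so these counts are not independent findings. Many medians moved with placebo replicate 2: without it they were -0.14 in macrophage, -0.24 in interferon, -0.34 in MHC class II, -0.095 in cytokine, -0.14 in complement and 0.017 in lymphocyte markers. Electron transport was then at 0.044 and the tricarboxylic acid cycle at 0.07, against -0.39 in the matrix and -0.2 in the cell cycle. The lymphocyte list was then not called, nor was it without sleeptime replicate 3 (-0.088), and the sarcomere list was lost without placebo replicate 2 (0.007) or sleeptime replicate 1 (0.036) and the sex-linked list without placebo replicate 1 (0.13). Without placebo replicate 1 the medians were -0.13 in fetal, 0.27 in ion channel and 0.076 in sarcomere genes, and without sleeptime replicate 3 the sex-linked median was 0.084.

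Of the 29469 genes, limma called 0 between sleeptime captopril and placebo, where 2895 had an unadjusted p under 0.05; it also called 0 with array weights, a robust variance, median centring or the set of array-name numbers as a covariate. The sleeptime and placebo arrays lie wholly in different sets of array-name numbers. Among the 1935 genes whose probe sets read as bright, chosen after seeing the data, 2 passed, Acta1 and Gm6180 (-0.35, named after its values were seen). Without placebo replicate 1 there were 15 calls, 13 lower and 2 higher, the latter Cyb5d2 and Ubxn2a. The values of the renin-angiotensin genes were -0.3 ± 0.14 for Ace and 0.27 ± 0.09 for Agtr1a, and those of Nppa and Nppb -0.39 ± 0.14 and -0.59 ± 0.2.

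**Figure D2:**
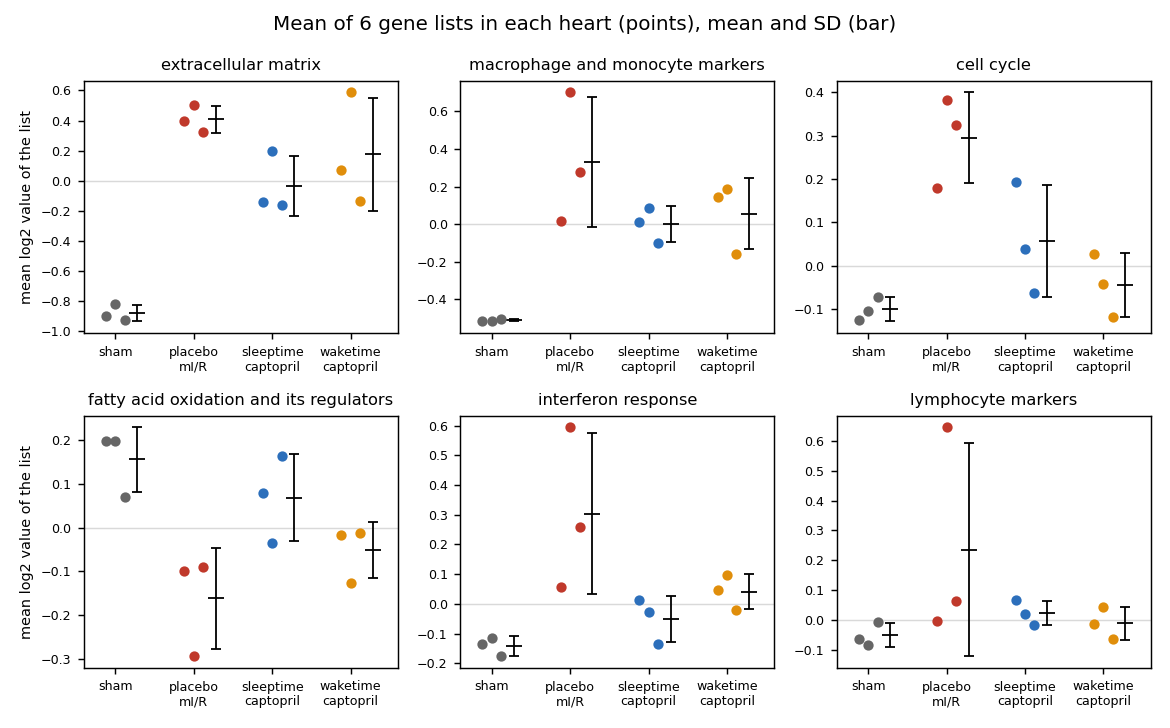
Mean log2 value of the members of 6 gene lists in each heart, with each gene's median over the 12 hearts at 0; points are hearts and bars the mean and SD of the 3 hearts of a group. The extracellular matrix mean lay between -0.923 and -0.822 in sham hearts and between 0.324 and 0.506 in placebo hearts, and the lymphocyte mean of placebo replicate 2 at 0.645.

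Waketime captopril was set against placebo to ask the same question for the other time of dosing. Again no gene passed, and the cell cycle list stood lowest among the lists with many members, at a median of -0.34 over 31 genes. Acta1 was at 0.35-fold of placebo (95% interval 0.26 to 0.48, n = 3 per group, adjusted p = 0.161) and Nppb at 0.55-fold (0.4 to 0.74; adjusted p = 0.292). Myh7 was at 1.28-fold (0.88 to 1.84; adjusted p = 0.828). The mitotic genes Ccnb2 and Cdk1 were at 0.52-fold each (0.37 to 0.71; adjusted p = 0.271) and Ccna2 at 0.63-fold (0.52 to 0.77; adjusted p = 0.261). Genes with the smallest p, all at an adjusted p of 0.161, also included Btnl9 (-0.34 ± 0.04), Ch25h (-0.44 ± 0.06), Mybl1 (-0.32 ± 0.04) and the actin-turnover gene Wdr1 (-0.3 ± 0.05). Higher were the cardiac transcription factor gene Tbx5 (0.51 ± 0.07), the cardiac myosin light chain kinase gene Mylk3 (0.41 ± 0.06), Ccrl2 (0.47 ± 0.07), AI317395 (0.47 ± 0.07) and Tob1 (0.32 ± 0.05).

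Camera called 20 lists between waketime captopril and placebo, 8 higher and 12 lower, and 0 with an estimated correlation. The cell cycle list was lower at a camera adjusted p of 6.89e-31, with an adjusted p = 0.18 with an estimated correlation and a fry adjusted p of 0.0422. Of its 31 genes 26 were lower adjusted over the list alone. Without placebo replicate 2 the unadjusted fry p of the cell cycle list was 0.0062, and without waketime replicate 2 it was 0.00457. Each was the smallest among the lists and too large to pass adjustment over them, so the fry call needed all hearts of both groups or the power they give. Interferon (median -0.29), cytokine (-0.12) and sex-linked genes (0.15) each had an adjusted p = 0.294 with an estimated correlation, as did ion channels (0.1). The fetal programme (-0.18; 4 genes lower adjusted over the list alone) and clock genes (0.09; Cry2 0.2, Nr1d2 0.2) each had an adjusted p = 0.25 with an estimated correlation. Complement (-0.26) had an adjusted p = 0.389 with an estimated correlation, and macrophage (-0.32), lymphocyte (-0.1), MHC class II (-0.48) and glucocorticoid response genes (0.17; Zbtb16 0.49) each had an adjusted p = 0.432 with an estimated correlation. The extracellular matrix (-0.21), fatty acid oxidation (0.092), neutrophil (-0.021), atrial (-0.098) and red blood cell lists (0.15) each had an adjusted p = 0.434 with an estimated correlation. Activated fibroblast markers (-0.1; adjusted p = 0.586 with an estimated correlation), the tricarboxylic acid cycle (0.054; adjusted p = 0.673 with an estimated correlation) and electron transport (0.041; adjusted p = 0.699 with an estimated correlation) completed the called lists. Adjusted over the list alone, 2 cytokine genes, 1 macrophage and 1 complement gene were lower and 2 sex-linked genes higher. Without placebo replicate 2 the medians were -0.28 in the cell cycle, -0.1 in macrophage, -0.13 in interferon, -0.085 in complement and -0.066 in cytokine genes. In that setting 9 lists were no longer called: electron transport (-0.023), tricarboxylic acid cycle (0.002), fatty acid oxidation (0.034), lymphocyte (-0.016), MHC class II (-0.1), activated fibroblast (-0.075), atrial (-0.036), neutrophil (-0.009) and glucocorticoid response (0.095). Calls of activated fibroblast (-0.001), electron transport (0.02), tricarboxylic acid cycle (0.023), neutrophil (-0.027) and sex-linked lists (0.1) were lost without waketime replicate 3, and that of the red blood cell list without placebo replicate 3 (0.12) or waketime replicate 1 (0.06). Activated fibroblast (-0.097) and atrial lists (-0.1) were also lost without placebo replicate 1, the tricarboxylic acid cycle (0.054) without waketime replicate 1, and atrial (-0.15) and neutrophil lists (-0.019) without waketime replicate 2. Waketime replicate 2 had the highest matrix mean of the 12 hearts, 0.588, and without it the medians were -0.43 in the matrix, -0.18 in activated fibroblast, 0.16 in ion channel, 0.16 in fatty acid oxidation, 0.12 in tricarboxylic acid cycle, 0.079 in electron transport and 0.11 in glucocorticoid response genes. Without waketime replicate 3 they were -0.071 in the matrix, 0.042 in fatty acid oxidation and -0.2 in macrophage markers, and without placebo replicate 1 -0.49 in macrophage, -0.76 in MHC class II, -0.4 in complement, -0.22 in cytokine, -0.054 in neutrophil, 0.07 in electron transport and 0.09 in sex-linked genes. Without placebo replicate 3 they were 0.2 in ion channel, 0.14 in fatty acid oxidation, 0.075 in electron transport, -0.15 in lymphocyte, -0.18 in atrial and -0.042 in neutrophil genes. Without waketime replicate 1 they were 0.23 in sex-linked, -0.16 in atrial and -0.034 in neutrophil genes, and without waketime replicate 3 the red blood cell median was 0.25.

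Limma called 0 of 29469 genes between waketime captopril and placebo, where 2209 had an unadjusted p under 0.05, and 0 with array weights, a robust variance or median centring. Within the lower set of array-name numbers, 2 waketime against 3 placebo hearts, 0 genes passed and the matrix median was -0.17. Among the 1935 bright genes 7 passed, with Acta1 and Wdr1 lower and Tbx5 and Mylk3 higher among them. Postn stood at -0.5 ± 0.21, Col3a1 at -0.61 ± 0.3, Nppa at -0.1 ± 0.14, Ace at -0.3 ± 0.14 and Agtr1a at 0.35 ± 0.09.

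Sleeptime and waketime captopril were compared to ask whether the time of dosing made a difference. All hearts were taken at the same hour, so the dosing time cannot be told apart from the time since the last dose. The largest difference among the genes with the smallest p was that of Myh7, at 0.38-fold in sleeptime hearts (95% interval 0.27 to 0.56, n = 3 per group, adjusted p = 0.788). Its means were -0.6 ± 0.2 (SD) in sleeptime and 0.78 ± 0.51 in waketime hearts. Btnl9, a butyrophilin-like gene, had the smallest adjusted p, 0.38, at 1.25-fold (1.17 to 1.33). Col3a1 (-0.02 ± 0.3 SE), Postn (-0.22 ± 0.21), Acta1 (0.23 ± 0.19), Nppa (-0.3 ± 0.14), Ace (0 ± 0.14) and Agtr1a (-0.08 ± 0.09) did not pass. The remaining genes with the smallest p, each at an adjusted p of 0.788, were Aen (0.25), Flrt1 (0.19), Grip2 (0.37) and Rpusd4 (0.26) on the higher side and Cep83 (-0.25), Gdf6 (-0.18), Pcnxl3 (-0.21) and Plcxd1 (-0.17) on the lower.

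No gene of 29469 was called by limma between the dosing times, and 1448 had an unadjusted p under 0.05, fewer than the 1473 expected by chance; array weights, a robust variance, median centring and the bright genes also gave 0. Camera called 13 lists, 7 higher and 6 lower in sleeptime hearts, and 0 of them with an estimated correlation. Of these lists 12 had an adjusted p = 0.651 with an estimated correlation and the interferon list an adjusted p = 0.676 with an estimated correlation. Adjusted over the list alone, 1 endothelial gene was lower and none of the other lists' members passed. The matrix (median -0.2; Ctgf -0.68), activated fibroblast (-0.11), immediate early (-0.11; Junb -0.27), interferon (-0.083), endothelial (-0.078; Tek -0.2) and clock lists (-0.044) were lower in sleeptime hearts. Fatty acid oxidation (0.11), the tricarboxylic acid cycle (0.086), electron transport (0.071), mast cell (0.067), cell cycle (0.063), ion channel (0.06) and sarcomere lists (0.036) were higher. Without waketime replicate 2 the matrix median turned to 0.007 and 10 lists were no longer called: matrix, activated fibroblast (-0.011), sarcomere (0.007), ion channel (0.012), electron transport (0.018), tricarboxylic acid cycle (0.018), clock (-0.017), endothelial (-0.041), interferon (-0.055) and immediate early genes (-0.049). Fatty acid oxidation was then at 0.063, and without waketime replicate 3 the matrix was at -0.38, activated fibroblast markers at -0.21, clock genes at -0.084, electron transport at 0.11, ion channels at 0.11 and sarcomere genes at 0.068. Calls were lost without sleeptime replicate 1 in activated fibroblast (-0.061), clock (-0.02), sarcomere (0.026), ion channel (0.058) and endothelial lists (-0.068), and without sleeptime replicate 2 in ion channel (0.063) and clock lists (-0.064). Without sleeptime replicate 3 they were lost in activated fibroblast (-0.073), sarcomere (0.038), ion channel (0.054), interferon (-0.044) and endothelial lists (-0.042), and without waketime replicate 1 in interferon (-0.065) and endothelial lists (-0.042). Still called were activated fibroblast markers at -0.19 and immediate early genes at -0.2 without sleeptime replicate 2, the cell cycle at 0.14 without sleeptime replicate 3, and ion channels at 0.11 and immediate early genes at -0.19 without waketime replicate 1. The cell cycle list was lost without sleeptime replicate 1 (0.027) or waketime replicate 3 (0.041) and the mast cell list without sleeptime replicate 2 (0.046) or waketime replicate 3 (0.033). Only fatty acid oxidation stayed called whichever heart was left out. The renin-angiotensin list was not called (median -0.038, camera adjusted p = 0.231), nor were macrophage markers (-0.057, camera adjusted p = 0.36). Within the higher set of array-name numbers, where 3 sleeptime hearts met 1 waketime heart and the spread came from the sham and sleeptime hearts, the matrix median was -0.084 and Myh7 was at -1.04.

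A score per heart summed up the genes that differed after mI/R, as the mean of the 1065 genes higher in placebo than in sham hearts minus the mean of the 623 lower ones. Its mean was 0.406 ± 0.155 (SD) in placebo, -0.045 ± 0.113 in sleeptime, 0.087 ± 0.16 in waketime and -0.499 ± 0.006 in sham hearts, n = 3 each. Sleeptime hearts scored -0.133 ± 0.113 (SE) from waketime hearts, a difference within the spread of the hearts (exact two-sided permutation p = 0.3, 20 splits, smallest possible 0.1). The placebo and sham means come from the hearts that chose the genes. Scored instead on the genes called between waketime and sham hearts, sleeptime hearts were at -0.296 ± 0.086 (SE) from placebo hearts (exact permutation p = 0.1, the smallest possible). Of the waketime arrays 2 lie with the placebo arrays in the lower set of array-name numbers. The sham and sleeptime arrays lie in the higher set. A difference between the sets would have the same sign, so this score cannot tell it from an effect of captopril.

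**Figure D3:**
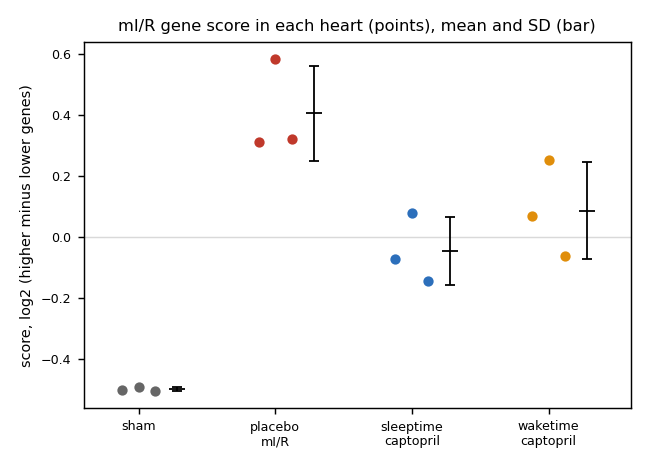
Score of each heart, the mean log2 value of the 1065 genes higher in placebo mI/R than in sham hearts minus that of the 623 lower genes; points are hearts and bars the mean and SD of the 3 hearts of a group. Sleeptime hearts lay at -0.071, 0.078 and -0.143 and waketime hearts at 0.07, 0.255 and -0.063.

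Pooling the dosing times gave 6 captopril hearts against 3 placebo hearts. Acta1 was at 0.38-fold of placebo (95% interval 0.3 to 0.5, adjusted p = 0.0724), the lowest of the genes with the smallest p; no gene passed. Ch25h (-0.49 ± 0.05 SE) and Mybl1 (-0.32 ± 0.04) had the same adjusted p. Oas1g (-0.65 ± 0.09), Adprhl1 (-0.23 ± 0.03), Tbx5 (0.46 ± 0.06), Mylk3 (0.37 ± 0.05), Ubxn2a (0.32 ± 0.04), Tob1 (0.31 ± 0.04) and Cyb5d2 (0.16 ± 0.02) followed at 0.0951. The cell cycle list was lower (median -0.3, camera adjusted p = 2.34e-26, fry adjusted p = 0.0443), with an adjusted p = 0.206 with an estimated correlation and 24 of 31 genes lower adjusted over the list alone. Without placebo replicate 2 its unadjusted fry p was 0.00859, the smallest among the lists and too large to pass adjustment over them. The fetal programme (-0.21; 7 genes lower adjusted over the list alone) also had an adjusted p = 0.206 with an estimated correlation. Interferon genes (-0.33; 13) had an adjusted p = 0.237 with an estimated correlation and the extracellular matrix (-0.35; 4) an adjusted p = 0.27 with an estimated correlation. Without placebo replicate 2 the interferon median was -0.18, and 7 of the 19 lists called by camera were lost. With an estimated correlation 0 of the 19 were called. Limma called 0 of 29469 genes, with 2804 at an unadjusted p under 0.05. Among the 1935 bright genes 34 passed, 22 higher and 12 lower, including Acta1, Nppb (-0.73), Tbx5 and Mylk3, and without placebo replicate 1 there were 33 calls over all genes, 4 higher and 29 lower.

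Across the 29469 genes, which are not independent replicates, the sleeptime and waketime differences from the shared placebo hearts correlated at r = 0.73, where unchanged groups gave 0.5 in 100 simulations. The covariance was 0.00888 against 0.00332. The sleeptime difference from placebo correlated with the placebo difference from sham at -0.79 (unchanged groups -0.5; covariance -0.0166 against -0.00332) and the waketime difference at -0.63 (-0.5; -0.0122 against -0.00334). With 3 placebo hearts the shared group could not be divided into parts of at least 2 hearts, so part or all of these excesses may come from the shared hearts. The simulated genes varied independently, unlike genes that move together within a heart. The simulations therefore cannot say how large an excess arises without an effect of captopril.

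Against sham, the matrix list was higher by camera in both captopril groups, with an adjusted p = 0.223 with an estimated correlation in sleeptime and an adjusted p = 0.192 with an estimated correlation in waketime hearts. In sleeptime hearts Postn was 4.91-fold higher (95% interval 3.58 to 6.74, n = 3 per group, adjusted p = 0.0142), the only gene called out of 29469, and 2862 genes had an unadjusted p under 0.05. Postn was not called without sham replicate 1, 2 or 3 (2.35, 2.32 and 2.22) or sleeptime replicate 2 or 3 (2.15 and 2.37), each of which left 0 calls, and 2 genes passed without sleeptime replicate 1. At an adjusted p of 0.0591 lay Col3a1 (2.24 ± 0.3 SE), Cilp (1.69 ± 0.22), the macrophage complement receptor gene Vsig4 (1.23 ± 0.15), Nppa (1.03 ± 0.14), Ccdc80 (1.01 ± 0.12) and Trem2 (0.82 ± 0.1). Myh7 was at 0.03 ± 0.24. Camera called 14 lists in sleeptime hearts, and 0 with an estimated correlation. The 14 were led by the matrix (median 0.72, 43 of 50 higher adjusted over the list alone) and activated fibroblast markers (0.35, 11 higher), each with an adjusted p = 0.223 with an estimated correlation. Macrophage markers (0.49; 14) and complement (0.35; 5) each had an adjusted p = 0.376 with an estimated correlation. Both groups lie in the higher set of array-name numbers, and fitted alone they gave 86 calls; array weights gave 23, and, chosen after seeing the data, probe sets of cross-hybridization type 1 alone 15 and the bright genes 31.

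In waketime hearts 316 genes differed from sham, 271 higher and 45 lower, with 4155 at an unadjusted p under 0.05. Postn was 5.72-fold (4.16 to 7.85, n = 3 per group, adjusted p = 0.00592), Col3a1 4.78-fold (3 to 7.61), Nppa 2.5-fold (2.01 to 3.13) and Myh7 2.66-fold (1.84 to 3.85; adjusted p = 0.0298) higher. Further large rises were those of Angptl7 (2.2), Sfrp2 (2.16), Cilp (2.05), Gpnmb (1.73) and Mfap5 (1.69). The largest falls were those of Penk (-0.73), Ces1d (-0.68), Kcnj3 (-0.5) and Cited2 (-0.49). Acta1 (0.19) and Timp1 (1.28, adjusted p = 0.0521) did not pass. Of the 18 lists called by camera, 0 were called with an estimated correlation. The matrix (median 0.91, 31 of 50 called, 47 adjusted over the list alone) and activated fibroblast markers (0.46, 7 of 20 called, 13) each had an adjusted p = 0.192 with an estimated correlation. Macrophage markers (0.51; 4 of 29, 20), complement (0.38; 3 of 16, 9) and endothelial markers (0.16; 4 of 23, 6) each had an adjusted p = 0.24 with an estimated correlation. Fatty acid oxidation was lower (-0.21; 0 of 28, 19; adjusted p = 0.298 with an estimated correlation), and the cell cycle list was not called (0.064, camera adjusted p = 0.0687). Of the 271 higher genes 226 were also called higher in placebo hearts, and of the 45 lower genes 33 were called lower there, where 100 simulations of unchanged groups shared 0 and independent lists would share 9.8 and 1. The simulation leaves out the effects, so few calls can arise in it and its 0 sets no scale for the overlap. The independent lists leave out the shared sham hearts. With 3 sham hearts, too few to divide, part or all of the excess over independent lists may come from them.

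The waketime count was 41, 35 and 0 without sham replicate 1, 2 or 3, 58 and 55 without waketime replicate 1 or 2, and 574 without waketime replicate 3. Without sham replicate 3 Postn was at 2.44 and Nppa at 1.38, and neither passed. Col3a1 and Myh7 were not called without sham replicate 1 (2.11 and 1.32), 2 (2.37 and 1.33) or 3 (2.29 and 1.59). Nor was Myh7 called without waketime replicate 1 (1.58) or 2 (1.12). The count was 0 in a fit of the waketime and sham hearts alone, 491 with array weights and 0 with the set of array-name numbers as a covariate. The higher set alone, with 8 calls, held 1 waketime heart, so that the spread came from the 3 sham and 3 sleeptime hearts and the count says little of the group. Of the matrix genes 6, 5 and 0 were called without sham replicate 1, 2 or 3 and 9 and 15 without waketime replicate 1 or 2. Without any 1 of these 5 hearts at most 1 activated fibroblast gene, 2 macrophage genes, 1 endothelial gene and 0 complement genes were called, and without waketime replicate 3 there were 3 lower fatty acid oxidation genes.

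All 9 mI/R hearts together differed from sham in 1059 genes, 738 higher and 321 lower. Postn was 6.1-fold (4.71 to 7.9, adjusted p = 0.000578), Nppa 2.39-fold (2 to 2.87) and Ace 1.44-fold (1.21 to 1.72, adjusted p = 0.0326) higher, with Ces1d at 0.66-fold and Penk at 0.61-fold. In this comparison 17 lists were called by camera, and 0 with an estimated correlation. Called higher were 41 of 50 matrix genes (median 0.91, adjusted p = 0.155 with an estimated correlation) and 16 of 29 macrophage markers (median 0.59, adjusted p = 0.214 with an estimated correlation). The matrix count was 25 and 26 without sham replicate 1 or 3. That of macrophage markers was 3, 6 and 3 without sham replicate 1, 2 or 3, 9 without sleeptime replicate 1 or 2 and 10 without waketime replicate 2. The count of all genes was 206, 412 and 240 without sham replicate 1, 2 or 3, 699 and 647 without sleeptime replicate 1 or 2, 470 among the bright genes and 16 with the set of array-name numbers as a covariate. Ace was not called without sham replicate 1, 2 or 3 (0.49, 0.6 and 0.5) or sleeptime replicate 1 (0.53), nor Penk without sham replicate 1, 2 or 3 (-0.71, -0.67 and -0.76).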

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

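The gene lists and their tests were planned; the tests on the probe sets left out of the main analysis were chosen only after the data were seen.

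The 2 captopril groups differed in 13 gene lists by camera, and in none with an estimated correlation. In sleeptime minus waketime hearts the list medians were -0.198 in the extracellular matrix, -0.109 in activated fibroblast markers, -0.105 in immediate early genes, -0.083 in interferon genes, -0.078 in endothelial markers and -0.044 in clock genes. They were 0.112 in fatty acid oxidation, 0.086 in the tricarboxylic acid cycle, 0.071 in electron transport, 0.067 in mast cell markers, 0.063 in the cell cycle, 0.06 in ion channels and 0.036 in sarcomere genes. Waketime replicate 2 carried most of the matrix difference: its matrix mean was 0.588, against 0.072 and -0.137 in the other waketime hearts and -0.139, 0.197 and -0.163 in the sleeptime hearts. Without it the matrix median was 0.007.

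Probe sets without a gene symbol or with several also held differences between placebo mI/R and sham hearts. Of these 4366 probe sets 79 passed the same limma test, 55 higher and 24 lower, and 589 had an unadjusted p under 0.05. In the other comparisons 1 passed higher in sleeptime, 15 higher and 8 lower in waketime and 36 higher and 15 lower in all mI/R hearts against sham, and 1 lower in either captopril group against placebo. None passed in sleeptime or waketime against placebo or between the dosing times.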

How the results depend on the processing

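Of the called list results, 134 of 136 kept their call with a replicate block and 136 with the probe set with the most probes, 31 kept it with fry and 0 with an estimated correlation. With 1 heart left out, 876 list results kept their call and direction, although some of their medians moved by over 1.5 times, 94 lost their call and 5 turned. Turned medians were 0.017 in lymphocyte markers (sleeptime against placebo; range -0.154 to 0.017), -0.023 in electron transport (waketime against placebo; -0.023 to 0.079) and 0.007 in the extracellular matrix (sleeptime against waketime; -0.377 to 0.007). Between waketime and placebo the direction of the camera test also turned for the tricarboxylic acid cycle (median 0.002; 0.002 to 0.121) and activated fibroblast markers (-0.001; -0.176 to -0.001).

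The counts of placebo against sham ranged from 712 to 1733 with 1 heart left out and those of sleeptime against sham from 0 to 2. Those of waketime against sham ranged from 0 to 574 and those of all mI/R groups against sham from 206 to 1416. For sleeptime and for either captopril group against placebo they ranged from 0 to 15 and from 0 to 33. The score difference between the dosing times ranged from -0.226 to -0.04. Fewer hearts lower the power, and why single hearts moved the counts further was not tested.

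With a replicate block the sleeptime and waketime counts against sham were 86 and 604, and with array weights 23 and 491. The labels do not say whether the replicate numbers pair the hearts, and they were not treated as pairs: residuals of hearts of the same number had a median correlation of 0.035 (18 pairs) against -0.015 (36 pairs), and 4 of 12 hearts were closest to their own number. A 1.5-fold minimum left 391, 119 and 177 genes in placebo, waketime and all mI/R hearts against sham, by its construction. Fits of the compared groups alone gave 1006, 86 and 0 genes in placebo, sleeptime and waketime against sham. A robust variance, median centring and the probe set with the most probes moved no count by over 1.5 times. For the other moves between settings the cause was not tested.

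Alternatives chosen after seeing the data moved further counts. Cross-hybridization type 1 alone gave 15 genes in sleeptime against sham. Bright probe sets alone, with fewer genes tested, gave 650, 31 and 470 in placebo, sleeptime and all mI/R hearts against sham, and 2, 7 and 34 in sleeptime, waketime and either captopril group against placebo. The set of array-name numbers as a covariate left 3, 0 and 16 genes in placebo, waketime and all mI/R hearts against sham; for the 1688 genes called in placebo against sham the median SE was 0.141 in place of 0.078. Within the higher set the sleeptime and waketime counts against sham were 86 and 8, the latter from 1 waketime heart, with the spread of the sham and sleeptime hearts.

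Among the named genes, values near 0 turned. With the number set as a covariate these were Agt 0.22, Bdkrb1 0.05 and Nr1d1 0.03 (placebo against sham) and Col3a1 0.34 (sleeptime against waketime, 0.02 with array weights). With 1 heart left out, Nr1d1 ranged from -0.15 to 0.08 and Dbp from -0.01 to 0.09 (placebo against sham). Col3a1 ranged from -0.25 to 0.39, Postn from -0.4 to 0.05 and Ace from -0.14 to 0.14 (sleeptime against waketime), and Myh7 from -0.08 to 0.21 (sleeptime against sham).

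Filters on dim probe sets, a variance trend and quantile normalization were not run, since the values hold no level, and the second file was identical. Signal over background could not be computed.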

Other observations

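All tests below except the splits were chosen only after the result was seen.

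Placebo replicate 2 differed from the other placebo hearts in immune genes, named here after their values were seen. The acute-phase gene Saa3 stood 3.35 higher on the log2 scale than the mean of the other placebo hearts, and the chemokine genes Ccl5, Cxcl13 and Cxcl9 2.46, 2.29 and 2.17 higher. The T cell receptor genes Trac and Cd3g were 2.22 and 2.16 higher and Jchain, which plasma cells express, 2.11 higher. Atrial markers differed within groups too, with list means of 0.379 in placebo replicate 2, -0.348 in placebo replicate 3 and -0.468 in waketime replicate 2, which also held the highest epicardial mean, 0.455.

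For the immune genes of placebo replicate 2, lymphoid tissue in the sample and a lower share of cardiomyocytes were weighed. B cell markers exceeded the other placebo hearts by 0.067 (SE 0.04 over 5 genes) and T cell markers by 0.698 (SE 0.311 over 6 genes). The small B cell excess goes against lymphoid tissue rich in B cells, while immunoglobulin genes such as Igkv12-46 (3) and Ighv1-34 (2.65) go with it. The SEs are over genes of 1 heart, and lymphoid tissue stayed open. The endothelial list stood at -0.034 and the matrix list at 0.148 where lymphocyte markers stood at 0.615, which argues against a lower share of cardiomyocytes as the whole cause. Sarcomere genes at -0.103 (SE 0.013), electron transport at -0.196 (SE 0.012), fatty acid oxidation at -0.199 (SE 0.018) and ion channels at -0.223 (SE 0.037) go with a lower share, which stayed open as a part. A stronger immune infiltrate in that heart was not tested.

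The score of the genes called between placebo and sham hearts, those higher less those lower, stood -0.452 from placebo in sleeptime captopril hearts, where no gene passed. On genes called between waketime and sham hearts, in a fit whose spread used all 12 hearts, the score difference was -0.296 (SE 0.086, exact two-sided permutation p = 0.1), and without placebo replicate 2 it was -0.253 (SE 0.075, exact permutation p = 0.2). Genes with the smallest p in a fit of the waketime and sham hearts alone, where 0 passed, gave -0.345 (SE 0.15, exact permutation p = 0.1). Each lay below 0 by more than its SE. The scores reuse the same hearts and the smallest possible p was 0.1. They therefore cannot exclude the choice of genes or that heart as the cause, and both stayed open. Less injured tissue in the sampled piece stayed open: cell cycle values less their placebo ratio to the matrix were -0.015 in 6 captopril and 0.17 in 3 placebo hearts (exact two-sided permutation p = 0.119, 84 splits). The ratio came from the placebo hearts tested, and the dosing times were pooled. The cell cycle list kept 40% of its placebo shift from sham in sleeptime and 14% in waketime hearts. The pooled value thus does not describe the sleeptime hearts alone. The set of array-name numbers stayed open as well, since the waketime heart of the higher set scored -0.026 from those of the lower set, against an SD of 0.16 among waketime hearts. Only 1 waketime heart lies in the higher set.

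Myh7, chosen for its size among genes that did not pass, was lower in sleeptime than in waketime hearts by 1.38. With the matrix score of each heart as a covariate the difference was -1.13 (SE 0.17, limma adjusted p = 0.796). As the choice for size keeps such a difference large, a different share of injured tissue stayed open. The atrial markers Sln, Myl4, Myl7 and Bmp10 had a mean of -0.816 in waketime minus sleeptime hearts (SE 0.35, exact two-sided permutation p = 0.1), and the 13 genes of the atrial list were 0.275 higher in sleeptime hearts on average. Atrial tissue in the waketime samples would give the opposite sign of these markers, which argues against it. Whether atrial tissue in the sleeptime samples played a part was not tested. With the set of array-name numbers as a covariate the difference in Myh7 was -1.04 (SE 0.32), and as only 1 waketime heart lies in the higher set the question stayed open.

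Splits of the hearts into other groups were counted for every comparison, with the real grouping among them. In placebo against sham 1 of 10 splits gave as many calls as the real 1688, with 0 in the highest other, and in waketime against sham 1 of 10 gave 316, with 1 in the highest other. Counting genes at an unadjusted p under 0.05, 1 of 10 splits reached the 2895 of sleeptime against placebo (highest other 1913) and 2 of 10 the 2209 of waketime against placebo (2739). For sleeptime against waketime 3 of 10 reached 1448 (2144), and for sleeptime against sham 1 of 10 reached 2862 (1559). With 10 splits a share under 0.05 cannot be reached. For either captopril group against placebo 4 of 84 splits reached 2804 genes, a share of 4.8%, just under 0.05 without a correction over the 8 comparisons, and the highest other gave 3521, so that chance was not firmly excluded. For all mI/R groups against sham 1 of 100 splits reached 1059 calls, the highest other giving 8, with subgroups drawn at random within each split.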
